A study of Mus musculus with 13 samples.

How the data were processed

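The series holds 13 arrays of total RNA from DMBA/TPA-induced squamous skin tumours, 6 from G9a WT and 7 from G9a cKO mice. Per the labels' protocols, 200 µl of DMBA at 0.25 mg/ml or TPA at 0.02 mg/ml was applied weekly for 6 weeks from 8 weeks of age, followed by TPA until at most 20 weeks. From TRIzol extracts, 25 ng of RNA was amplified by whole transcriptome amplification with 17 cycles, and 8 µg of cDNA was fragmented and labelled with biotin. Groups and replicate numbers come from the sample titles. The replicate numbers 2, 6, 8 and 9 occur in both groups, and no label says that they mark a shared mouse, litter or day.

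The deposited values are log2 expression per probe set after RMA (background correction, quantile normalization and probe-set summary), per the submitters' processing notes. The RMA version, the chip description, hybridisation dates and any later adjustment are not given in the sources used here. In the deposited log2 values, arrays that follow one another within a group mirror each other around the group mean, and no label records an adjustment in pairs. No scanner files or detection calls were used here. Of 45141 probe sets, 104 are array controls, 28898 have 1 gene symbol in the platform annotation, 551 have several and 15588 have none. Of those with 1 symbol, 28689 were found by gene number in the mouse annotation (GRCm38.p6), which changed 0 symbols and was used otherwise only for which genes neighbour each other. The probe sets with 1 symbol cover 17097 genes.

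Each gene was read by its probe set of highest mean over all arrays, with no filter on dim probe sets. Group differences (cKO minus WT) were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default prior, no covariate), two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Ehmt2 was tested by exact permutation over all splits of 13 arrays into 6 and 7. Named genes followed a rule fixed before the data were examined: Ehmt2, the 14 largest increases and 14 largest decreases among called genes (leaving out predicted, clone-named and sex-linked genes), and up to 4 members of each gene list by smallest p. All probe sets of named genes were looked at. Among the list members, Cd22, Rasgrf1, Ttk and Zbtb46 had another probe set called in the opposite direction.

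The 41 gene lists (953 symbols, 838 of them measured) were also fixed before the data were examined. Lists with at least 5 measured genes were tested with limma's camera (preset correlation 0.01, Benjamini-Hochberg over the lists), with fry as a self-contained test and camera with an estimated correlation as an alternative. Background was judged from the 23 nonspecific control probe sets, which span GC numbers 3 to 25 and group means of 3.01 to 6.32. Distances between tumours were 1 minus Pearson's r over the 2000 most variable genes.

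The script for the fits was tested on simulated values of 17097 genes with 200 changed. With independent arrays, 4.9% of unchanged genes had p under 0.05 and 15 were called, and 64% of genes changed by 0.5 and 86% of those changed by 1 on the log2 scale were recovered. In the deposit, neighbouring arrays mirror each other in part. When the simulated arrays were centred exactly in neighbouring pairs, 14.8% of unchanged genes had p under 0.05 and 345 were called. A term for each neighbouring pair brought this to 4.88% and 13 calls, with 34% of changes of 0.5 and 84% of changes of 1 recovered. The simulated arrays held no effect of pair or batch. The simulation therefore does not show that the error rate of either fit holds for the deposited values. The fit without the term stayed the main one, as fixed, and the counts are given with both.

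Alternatives fixed beforehand were median centring, quantile normalization of the deposited values, filters on genes below the 25th or 50th percentile, the mean over probe sets, each probe set on its own, a trended robust prior, array weights, the replicate number as a block, covariates for sex-linked expression and for cell makeup (the means of the fibroblast and macrophage lists), each array left out, and other thresholds. The neighbouring-pair term, alone and after quantile normalization, was added after seeing the data. No array pair held identical values, and correlations between arrays over genes lay between 0.968 and 0.995. Figures were drawn with matplotlib 3.10.9.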

Results

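Gene expression was measured on arrays in skin tumours that had been induced chemically in G9a WT mice and in G9a cKO (conditional knockout) mice. G9a, a histone methyltransferase, is encoded by Ehmt2 and places methyl groups on lysine 9 of histone H3, a mark of silent chromatin. The carcinogen DMBA and the tumour promoter TPA were applied to the back skin from 8 weeks of age, and each array came from a squamous tumour of a G9a WT mouse (n = 6) or of a G9a cKO mouse (n = 7). The title of the series speaks of chromatin accessibility, genomic instability and aggressiveness after G9a loss, and the arrays allow 1 comparison, cKO against WT tumours. Array medians were close, between 5.09 and 5.14 on the log2 scale. The spread of values differed by group: the SD over all probe sets was 1.91 to 1.94 on WT arrays and 1.83 to 1.88 on cKO arrays. The number of arrays limits the precision. The labels do not state whether each tumour came from a different mouse, so p-values concern these samples only. Neighbouring arrays mirror each other around their group mean, so p-values do not measure the full spread between tumours either.

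Ehmt2 itself was read by a pair of probe sets that differed in outcome. The second probe set (number 2) fell from 8.33 ± 0.19 (SD, n = 6) in WT to 6.01 ± 0.10 (SD, n = 7) in cKO tumours, a log2 change of -2.33 or 5.02-fold, with no overlap between the groups (8.03 to 8.61 against 5.87 to 6.12). The two-sided exact permutation p over all splits of the arrays was 0.000583, and the limma adjusted p over all probe sets was 9.7e-10. Probe set 1 read 7.29 ± 0.19 in WT and 7.42 ± 0.04 in cKO tumours, a change of 0.13 (exact permutation p = 0.131, n = 6 and 7). After quantile normalization its difference was 0.24 (limma adjusted p = 0.0145), and without WT replicate 9 it was 0.17 (limma adjusted p = 0.0486). Where either probe set lies relative to the deleted part of the gene is not given in the sources used here, and a probe set outside that part checks nothing.

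Collagens, leukocyte surface proteins and several genes that were close to background in WT tumours had the largest increases in cKO tumours among genes open to the naming rule. The fibrillar collagen genes Col3a1 and Col1a1 rose 9.33-fold and 7.64-fold, from 5.67 ± 1.07 to 8.89 ± 0.58 and from 6.25 ± 0.82 to 9.19 ± 0.52 (log2, SD, n = 6 and 7). Cd53, a leukocyte tetraspanin, rose 7.75-fold, the MHC class II chain gene H2-Ab1 rose 5.84-fold and the chemokine gene Ccl1 rose 5.72-fold. Gpa33, a surface glycoprotein best known from intestinal epithelium, rose 8.18-fold, from 6.23 ± 0.64 to 9.26 ± 0.34. Rgs7bp rose 8.09-fold, the aldo-keto reductase gene Akr1c13 7.58-fold and the retinoic acid binding protein gene Crabp1 5.96-fold. Gadl1, Trim30d, Xlr and Pate14 lay below the median of the nonspecific control probe sets on all 6 WT arrays, so only bounds can be given: they were at least 3.27-fold, 3.32-fold, 2.62-fold and 2.73-fold higher in cKO tumours. The neuropeptide precursor gene Cartpt lay below that median on 4 of 6 WT arrays and was at least 4.10-fold higher. All such bounds set the dimmer group, array by array, at the higher of its own value and 4.31, the upper quartile of the nonspecific controls. Of 187 named genes, 44 had a dimmer group with a mean below that level, and differences of such genes given without a bound are as measured. Other probe sets of Col3a1, Cd53 and Trim30d, all with WT means between 3.29 and 3.73, moved the same way by 0.28, 0.15 and 0.16 to 0.93. Within their groups, Gadl1 stood apart in cKO replicate 1 (6.24) and Col1a1 in WT replicate 8 (7.78). With the means of the fibroblast and macrophage lists as covariates, Col3a1 and Col1a1, which belong to the first of these lists, lost their calls, and H2-Ab1 had a change of -0.13 (adjusted p = 0.917). These covariates of cell makeup are built from genes that differ between the groups. Calls lost or directions turned with them, here and below, therefore do not measure a change at equal cell makeup.

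The largest decreases among genes open to the naming rule were those of Sprr2d, Tll1 and Inhba. Sprr2d, which encodes a small proline-rich protein of the cornified envelope, fell from 10.69 ± 1.51 to 7.05 ± 1.59 (log2, n = 6 and 7), a change of -3.65. Ereg and Nrg1, which encode ligands of EGF receptor family members, had log2 changes of -2.36 and -2.10, from 9.47 ± 0.62 to 7.10 ± 0.28 and from 9.38 ± 0.47 to 7.28 ± 0.31. Inhba, the gene of the activin A subunit, fell from 10.26 ± 0.62 to 7.63 ± 0.62. The adhesion gene Nectin3 (-2.21), the forkhead factor gene Foxq1 (-2.18), Kctd12 (at least 4.61-fold), Cpeb2 (-1.89) and Rassf8 (-1.85) also fell. Sprr2h (-2.13), Adgrl3 (-1.84) and Lgi2 (-1.94) passed the test only without the neighbouring-pair term described with the counts, with adjusted p of 0.060, 0.057 and 0.13 with it. The metalloprotease gene Tll1 lay below the control median on 2 of 7 cKO arrays and the cilia gene Cfap43 on 4 of 7, and they were at least 4.54-fold and 2.48-fold lower in cKO tumours. Other probe sets of Inhba (-0.20), Foxq1 (-0.39, adjusted p = 0.057), Lgi2 (-0.82, adjusted p = 0.28) and Nectin3 (-0.07 to -1.40) showed smaller differences. Nectin3 stood apart in WT replicate 9 (8.88). Sprr2d, Sprr2h, Kctd12, Foxq1, Lgi2 and Rassf8 lost their calls with the covariates of cell makeup.

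Of 17097 genes, 7830 (45.8%) differed between cKO and WT tumours at an adjusted p under 0.05 (limma): 4386 were higher and 3444 lower in cKO. Over 2-fold changes were far fewer, 304 genes, of which 160 were higher and 144 lower. After quantile normalization 4760 genes were higher and 2871 lower, and 171 and 112 over 2-fold. The groups did not overlap for 3924 genes (22.95%). Chance gives 0.117% for independent arrays, a rate that does not hold where arrays mirror each other. Within each group, arrays next to each other in the deposit mirrored one another, with correlations of their deviations from the group mean between -0.956 and -0.88 in all 6 such pairs. The SD of the pair means was 0.0348 to 0.0531 and that within pairs 0.20 to 0.216. With each neighbouring pair as a term, an alternative chosen after seeing the data, 4228 genes passed, 2459 higher and 1769 lower, all of them among the 7830, and 253 of the 304 over 2-fold changes passed as well. Single genes are said to have risen or fallen only where both fits called them, and the counts given for gene lists are those without the pair term. With the covariates of cell makeup 3249 genes passed.

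Array controls differed between the groups as well. For 23 nonspecific control probe sets, the difference went from 0.08 at low GC number to -0.307 near the highest. Of the called genes, 4423 (56.5%) changed by no more than 0.307 and 3407 by more. The 16 hybridisation control probe sets differed too, all higher on cKO arrays, by 0.0619 to 0.493. A change above 0.307 is therefore not always larger than the differences of controls. Changes of a size within these ranges, named above or below, are not set apart from differences of controls.

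**Figure D1:**
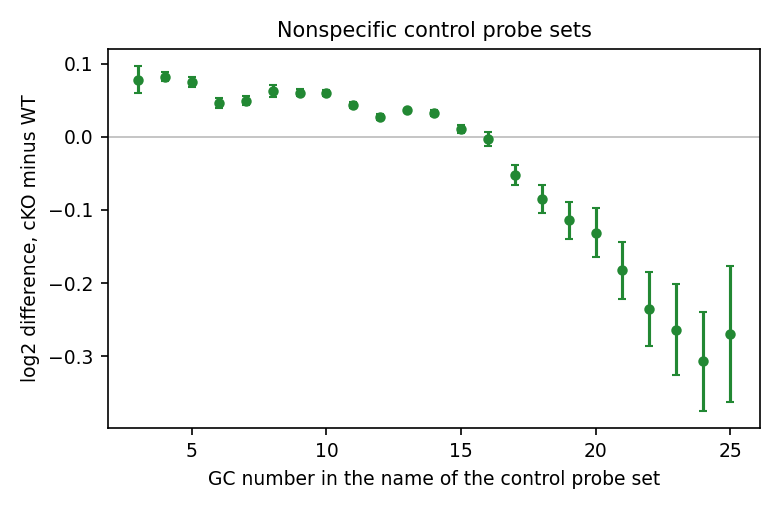
Log2 difference, cKO minus WT arrays, of each nonspecific control probe set (points, with standard error) against its GC number. The difference lies near 0.08 at the lowest GC numbers and reaches -0.307 near the highest.

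Many but not all markers of connective tissue and vessels were higher in cKO tumours. Of 25 fibroblast and collagen genes, 14 were higher and 1 lower (14 and 1 adjusted over the list alone), 9 of them over 2-fold, with a median log2 change of 0.57. Of the 25, 16 lay above background, with a group mean of at least 5.31. The abundant members Postn and Fbln1, outside the naming rule, did not pass, with values under the other observations. Besides the collagens, the dermal matrix gene Dcn rose by 1.10, Mfap5 by 0.54 and the surface glycoprotein gene Thy1 by 1.42. Dpt, below the control median on 6 of 6 WT arrays, was at least 1.28-fold higher in cKO tumours. Of 20 endothelial markers, 13 were higher and 2 lower (13 and 2 adjusted over the list alone), with a median of 0.52. Pecam1, the endothelial adhesion molecule CD31, rose from 5.83 ± 0.48 to 7.59 ± 0.41, and Tie1, Esam and the transcription factor gene Erg rose by 1.26, 1.18 and 0.41. With the pair term, 13 fibroblast genes were higher and none lower, and 10 endothelial genes higher and 1 lower. Both lists passed limma's camera test with a preset correlation of 0.01, at adjusted p of 0.000693 and 0.0131. With an estimated correlation the adjusted p was 0.866 for both. With the covariates of cell makeup, camera's direction for the endothelial list turned, with an adjusted p of 0.858. The fibroblast list, which enters a covariate itself, had an adjusted p of 0.768, and Thy1, Pecam1, Tie1 and Esam lost their calls.

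Interferon response genes were also higher, and MHC class II genes did not pass camera as a list. Of 29 interferon response genes, 17 were higher and 1 lower (17 and 1 adjusted over the list alone), with a median log2 change of 0.45 and a camera adjusted p of 0.000693, which became an adjusted p of 0.866 with an estimated correlation and 0.476 with the covariates of cell makeup. Zbp1, a sensor of nucleic acids, rose from 4.75 ± 0.08 to 6.44 ± 0.17, and Trim30a, Parp9 and Dhx58 rose by 1.11, 0.87 and 0.58. The WT mean of Trim30a, 3.68, lay below 4.31, the upper quartile of the nonspecific controls, so its difference is as measured and not a bound. Of 8 class II genes, 5 were higher and 1 lower (5 and 1 adjusted over the list alone): besides H2-Ab1, H2-Eb1 rose by 2.10, the invariant chain gene Cd74 by 2.01, H2-Aa by 1.61 and H2-DMa by 0.52. This list's median was 1.06, and its camera adjusted p of 0.0822 missed the threshold, while its fry adjusted p was 0.000159. Of 14 class I genes, 1 was higher (H2-M3, 0.65) and 1 lower (Tapbp, -0.43), and the list did not pass (adjusted p = 0.762). With the covariates of cell makeup Cd74, H2-Aa and H2-M3 lost their calls, and the class I list turned to a median of -0.47 (adjusted p = 0.0134).

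Among the keratinocyte lists, that of the stress set had the largest median difference. Of 20 genes of hyperproliferative and stressed keratinocytes, 6 were lower and 1 higher (6 and 1 adjusted over the list alone), with a median of -0.40 and a camera adjusted p of 0.0237 (adjusted p = 0.866 with an estimated correlation, and 0.101 with the covariates of cell makeup). Besides Sprr2d, Sprr1b fell from 9.90 ± 0.24 to 8.67 ± 0.66 and the keratin gene Krt6a fell by 0.37. With the pair term 3 members were lower and none higher. Sprr1b and Krt6a lost their calls with the covariates of cell makeup. Leaving out WT replicate 2 gave this list an adjusted p of 0.0518. Among 19 basal keratinocyte genes, 1 was higher and 3 lower, with a median of -0.01 (adjusted p = 0.519). Krt5 rose by 0.13, from 12.62 to 12.75, and Krt14 differed by -0.12. Hybridisation controls with WT means of 12.60 and 12.31 were higher on cKO arrays by 0.062 and 0.136. The rise of Krt5 is therefore not set apart from differences of controls. Of 37 suprabasal and cornified envelope genes, 5 were higher and 4 lower. Its median was 0.003 while camera's direction was down (adjusted p = 0.925), and Lce3c fell by 0.51. Dsg1a, below the control median on 4 of 6 WT arrays, was at least 1.15-fold higher in cKO tumours. Hair follicle genes (4 higher and 2 lower of 27, adjusted p = 0.925) and sebaceous gland genes (2 higher and 1 lower of 16, adjusted p = 0.925) did not pass as lists. Their medians were 0.02 and 0.07, with camera's direction up, and their means -0.04 and -0.02.

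**Figure D2:**
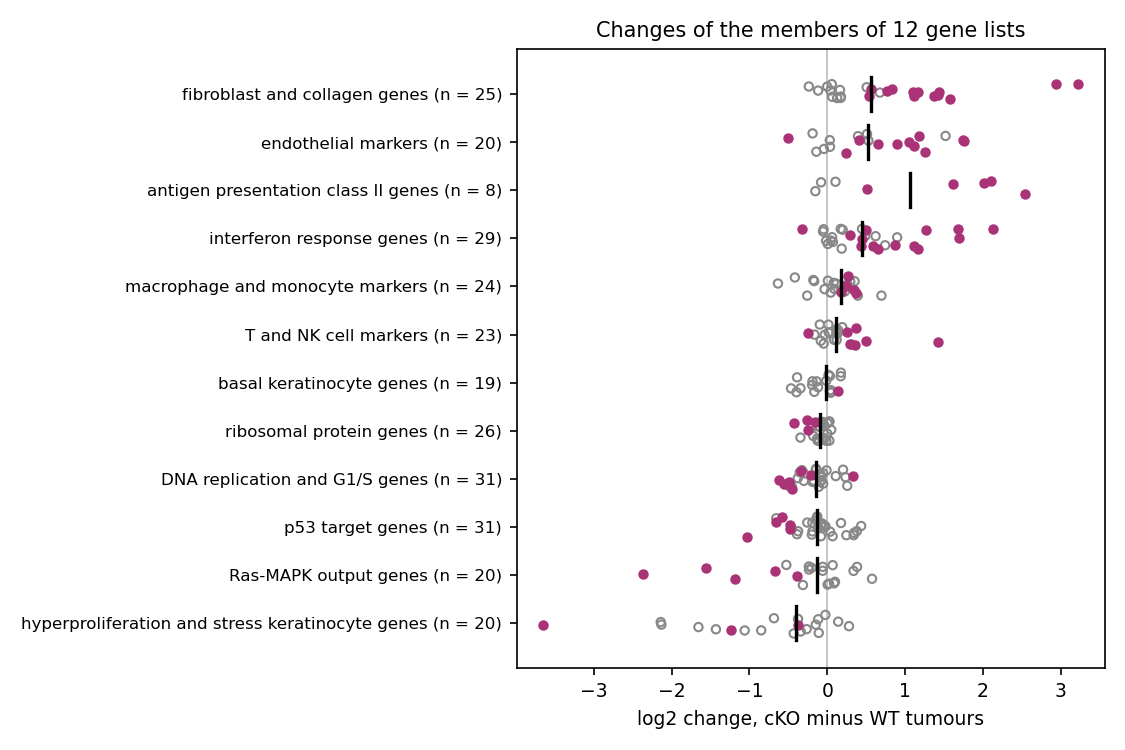
Log2 change, cKO minus WT tumours, of each measured member of 12 gene lists fixed beforehand (points). Filled points passed both fits, with and without the neighbouring-pair term, open points did not, and the black bar is the list's median, 0.57 for fibroblast and collagen genes and -0.40 for stress keratinocyte genes.

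Genes that mark invasion and loss of epithelial character went both ways. Of 21 inducers and mesenchymal genes of the epithelial-mesenchymal transition, 5 were higher and 5 lower. Snai2, a transcription factor gene of this programme, fell from 8.16 ± 0.14 to 6.74 ± 0.11 and the integrin gene Itga5 fell by 1.16, whereas Snai1 rose by 0.29, from 4.13 to 4.42, and Lox by 0.21. The WT mean of Snai1 lay below 4.31, the upper quartile of the nonspecific controls. Neither increase exceeded 0.307, the largest difference of a nonspecific control between the groups. This list's median was 0.05 and camera's direction was down (adjusted p = 0.925). Of 24 epithelial junction genes, 7 were lower and 3 higher (adjusted p = 0.249): Ocln, Tjp1 and Cdh1, which encode occludin, a tight junction scaffold and E-cadherin, fell by 1.04, 0.75 and 0.56, while Pkp2 rose by 0.58 on 1 probe set and differed by -0.002 (adjusted p = 0.983) on another. Of 26 matrix protease and invasion genes, 5 were higher and 7 lower (adjusted p = 0.249). Mmp11 rose from 4.13 ± 0.17 to 5.52 ± 0.20. Among 18 simple and mucosal epithelial genes of malignant progression, 4 were higher and 1 lower (adjusted p = 0.671). Muc1 rose by 1.13 and Elf3 fell by 0.98.

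DNA replication genes were lower and mitotic and repair genes mixed. Of 31 replication and G1/S genes, 12 were lower and 1 higher (12 and 1 adjusted over the list alone), with a median of -0.15 and a camera adjusted p of 0.0131 (adjusted p = 0.866 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, fell by 0.62, the licensing factor gene Cdt1 by 0.33 and Fen1 by 0.46. Another Cdt1 probe set differed by -0.04 (adjusted p = 0.0931). With the pair term 6 were lower and 1 higher. Of 30 mitosis genes, 4 were higher and 4 lower (adjusted p = 0.479), and Kif2c rose by 0.54. Ttk rose by 0.63 on 1 probe set and fell by 0.16 on another. Of 32 homologous recombination and Fanconi genes, 10 were higher and 7 lower (adjusted p = 0.925). Brca1 rose by 0.65, from 6.50 ± 0.20 to 7.15 ± 0.19, and Mre11a by 0.35, while Nbn fell by 0.48. Other probe sets of Brca1 differed by -0.23, 0.06 and 0.27 (adjusted p = 0.0748, 0.158 and 0.041) and that of Mre11a by 0.07 (adjusted p = 0.372). Of 26 ribosomal protein genes, 12 were lower and none higher (12 adjusted over the list alone), with a median of -0.10 and an adjusted p of 0.00854 (adjusted p = 0.866 with an estimated correlation). Rps13 fell by 0.42 and Rpl12 by 0.25, another Rps13 probe set differed by 0.06 (adjusted p = 0.386), and 4 members were lower with the pair term. After quantile normalization of the deposited values, the replication list's median was -0.07 (adjusted p = 0.141) and that of the ribosomal list -0.005 (adjusted p = 0.357). Without it, all genes in the highest decile of level had a median of -0.115. The ribosomal median, at a mean WT level of 11.4, was thus no lower than that of bright genes. For replication genes, with a mean WT level of 7.42, the decile of mean level 7.51 had a median of -0.078.

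Outputs of p53 and Ras signalling contained more lower than higher genes. Of 31 p53 targets, 8 were lower and 1 higher (6 and 1 adjusted over the list alone), and Plk2, Mdm2 and Xpc fell by 1.04, 0.65 and 0.58. Of 20 Ras-MAPK output genes, 6 were lower and 1 higher (6 and 1 adjusted over the list alone). Besides Ereg, Dusp4, a phosphatase gene induced by the pathway, fell from 8.83 ± 0.39 to 7.27 ± 0.72 and the EGF receptor ligand gene Epgn from 10.64 ± 0.36 to 9.46 ± 0.40. Neither list passed camera (adjusted p = 0.111 and 0.127). limma's fry, which asks whether a list's genes move one way without comparing them with other genes, gave adjusted p of 0.00477 and 0.0127. In all, fry called 14 lists higher and 7 lower, so passing it does not set these lists apart. The lists' medians were -0.13 each, and all genes in the 3 highest deciles of level had medians of -0.078, -0.114 and -0.115, which were 0.0492, 0.0388 and 0.0204 after quantile normalization. Notch pathway genes (3 higher and 5 lower of 15, median 0.04, camera's direction down, adjusted p = 0.712) included Dll4, up by 0.63, and Maml1, Dll1 and Jag1, down by 0.76, 0.76 and 0.48, with another Maml1 probe set at -0.04 (adjusted p = 0.689). Of 16 Wnt targets, 3 were higher and 2 lower (adjusted p = 0.831), with Apcdd1 and Axin2 up by 0.77 and 0.47 and another Axin2 probe set at 0.07 (adjusted p = 0.510). Of 22 hypoxia and glycolysis genes, 6 were higher and 1 lower (adjusted p = 0.479), and Egln3 and Bnip3 rose by 0.93 and 0.78. Of 20 xenobiotic and oxidative stress genes, 6 were lower and 1 higher (adjusted p = 0.126), and Tiparp and Gsto1 fell by 0.80 and 0.74. With the covariates of cell makeup this list's median was -0.36 (adjusted p = 0.0134).

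Chromatin genes and genes that silent chromatin often covers showed small changes with a few exceptions. Of 21 genes of the H3K9 methylation machinery, 11 were lower and 4 higher (adjusted p = 0.249). Setdb1, another H3K9 methyltransferase gene, rose by 0.30, with another probe set at -0.15 (adjusted p = 0.232), and the demethylase gene Kdm3a fell by 0.51. Of 32 germline and cancer-testis genes, 9 were higher and 4 lower (adjusted p = 0.653). Rhox5, a homeobox gene of the reproductive tract, rose from 5.61 ± 0.27 to 7.96 ± 1.23, and Mov10l1 and Brdt rose by 0.36 and 0.33 to cKO means of 5.35 and 5.03. Ddx4 lay below the control median on all arrays of both groups. Of 19 imprinted genes, 7 were higher and 2 lower (adjusted p = 0.519), and the noncoding RNA gene Meg3 rose by 1.03, from 5.86 ± 0.19 to 6.89 ± 0.26, on its brightest probe set. Other Meg3 probe sets moved less, and those that did not pass differed by 0.006, 0.02, -0.02 and 0.04.

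No list of markers of a single immune cell type passed camera. Macrophage (8 higher and 3 lower of 24, adjusted p = 0.249), neutrophil (7 and 0 of 16, adjusted p = 0.249), T and NK cell (10 and 2 of 23, adjusted p = 0.115), dendritic and Langerhans cell (1 and 4 of 12, adjusted p = 0.359), B cell (3 and 1 of 10, adjusted p = 0.519) and mast cell lists (5 and 1 of 10, adjusted p = 0.374) did not pass. All 6 passed fry, with adjusted p of 0.0333, 0.00413, 4.6e-06, 0.0312, 0.00544 and 1.5e-05 in that order. Passing fry does not set these lists apart, since of all lists tested it called 14 higher and 7 lower. Among those were the germline, skeletal muscle, adipocyte and melanocyte lists (fry adjusted p = 0.000118, 0.00208, 0.00189 and 0.0463). The named members of the 6 immune lists went both ways. Csf1r rose by 0.26, Adgre1 by 0.35, Foxp3 by 0.49, and Cd3g by 0.35, with cKO means between 4.28 and 5.77, and Thy1, on the T and NK cell list as well, reached 7.19. Both group means of Adgre1 and the WT mean of Foxp3 lay below 4.31, the upper quartile of the nonspecific controls. Ccl17 fell by 0.28, and Zbtb46 and Cd22 fell by 0.58 and 0.22, each with another probe set called higher. Fscn1, with a cKO mean of 10.69, differed by -0.49 (adjusted p = 0.063 with the neighbouring-pair term), and its other probe sets by -0.93 to 0.003. Of 26 inflammatory cytokine and chemokine genes, 5 were higher and 6 lower (adjusted p = 0.519): Cxcl1 and the prostaglandin synthase gene Ptgs2 fell by 1.41 and 1.25, and Csf1 rose by 0.51, while those of its probe sets that did not pass differed by 0.15 and -0.02. Skeletal muscle (5 higher and 3 lower of 19, adjusted p = 0.671), adipocyte (4 and 3 of 11, adjusted p = 0.717), melanocyte and Schwann cell (3 and 2 of 10, adjusted p = 0.717) and red blood cell lists (2 and 1 of 5, adjusted p = 0.717) did not pass camera. Neither did oxidative phosphorylation (1 and 3 of 28, adjusted p = 0.359) or immediate early and dissociation stress genes (2 and 1 of 21, adjusted p = 0.926), although the latter's median was -0.23 (adjusted p = 0.00713) with the covariates of cell makeup. Aqp7, an aquaglyceroporin gene on the adipocyte list, rose by 2.04. Of the 4 sex-linked genes, the Y-linked Eif2s3y fell from 8.45 ± 0.14 to 6.33 ± 0.92 and Xist read 6.12 ± 0.97 in WT and 4.96 ± 0.56 in cKO tumours (adjusted p = 0.031, and 0.090 with the neighbouring-pair term). Kdm5d and Uty differed by -0.28 and 0.05 (adjusted p = 0.207 and 0.799). Other probe sets were called lower, by -0.35 and -0.52 for Kdm5d (adjusted p = 0.00384 and 0.00943), -0.20 for Uty (adjusted p = 0.00500) and -0.24 for Eif2s3y (adjusted p = 0.00499), while those of Xist differed by -0.42 and -0.04 (adjusted p = 0.288 and 0.807). The labels do not give the sex of the mice.

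For lists without a count adjusted over the list alone above, that count equalled the one over all genes, except for germline (8 higher and 3 lower adjusted over the list alone), basal keratinocyte (1 and 1), hair follicle (3 and 1), matrix protease (5 and 9), mitosis (3 and 3), dendritic cell (1 and 5), immediate early (2 and 0) and oxidative phosphorylation genes (0 and 1). Across the 40 lists tested camera called 3 lists higher and 3 lower. That number sets no list apart from chance regroupings: 75 of 100 splits of the same arrays, the real one included, called as many, up to 16. With neighbouring arrays kept together and the pair term, 24 of 35 splits did, up to 14. No list held its call with an estimated correlation.

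The arrays cannot tell whether the genotypes differ in how far tumours lay from each other, because neighbouring arrays mirror each other. The median pairwise distance (1 minus Pearson's r over the 2000 most variable genes) was 0.0764 among cKO and 0.0853 among WT tumours, a difference of -0.0089 (two-sided exact permutation p = 0.706). Over all genes it was -0.00498 (exact permutation p = 0.0332). Without cKO replicate 1, the cKO array that has no paired neighbour, the cKO median was 0.1617 and the difference 0.0756 (exact permutation p = 0.0043). Distances include those between mirrored neighbouring arrays, while the permutation treats all arrays alike, so its p-values do not measure a difference between tumours.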

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

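The tests of an adjustment in neighbouring pairs, of the GC trend of the nonspecific controls and of strain sequence flanking Ehmt2 were chosen only after the result was seen, and so were parts of the rules by which the keratinocyte share and the chromosome segments were judged.

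An array stood far from the rest of its group in 3 of 146 groups of values examined. Chance gives about 1 in 20 for independent arrays, a rate that does not hold for arrays that mirror each other. Gadl1 read 6.24 in cKO replicate 1 and 5.97 to 5.99 in the other cKO tumours. Col1a1 read 7.78 in WT replicate 8 and 5.29 to 6.18 in the other WT tumours. Nectin3 read 8.88 in WT replicate 9 and 7.59 to 8.01 in the other WT tumours. WT replicates 8 and 9 are a mirrored pair: Col1a1 was lowest in WT replicate 9 (5.29) and Nectin3 in WT replicate 8 (7.59). A far value in this pair can therefore not be assigned to a single tumour. Among the cKO arrays, replicate 1 is the only array without a paired neighbour.

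Probe sets outside the gene comparison also differed between the groups. All 16 hybridisation control probe sets were higher on cKO arrays at an adjusted p under 0.05 (limma), by 0.0619 to 0.493 and a median of 0.307 on the log2 scale. The nonspecific control of highest GC number differed by -0.2695. Among 16139 probe sets without a single gene symbol, 191 changed over 2-fold, 60 higher and 131 lower in cKO.

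The first pattern is the number of genes changed. For it 1 of 100 splits of the arrays, the real one, gave 7830 genes and the highest other gave 8. With neighbouring arrays kept together and the pair term 1 of 35 splits, the real one, gave 4228 and the highest other 2552. These splits cannot exclude chance, because neighbouring arrays mirror each other around the mean of their own group. Every other split mixes those means. An adjustment of arrays in neighbouring pairs that understates the spread stays open, since the deviations of the arrays in each of the 6 pairs correlated at -0.88 or lower, and each pair holds 1 group, so pair and group effects share the same arrays. A background that depends on GC and differs between the groups stays open too: over 23 nonspecific controls, which are not independent samples, the difference fell with GC number (Pearson's r = -0.92, Spearman's rho = -0.979, permutation p = 1e-05 for each, the smallest that 100000 resamples can give; r = -0.914 without the 2 farthest and -0.588 after quantile normalization). The loss of G9a stays open as a biological explanation, and array batch and group cannot be told apart because no label gives batches or dates.

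The second pattern is the higher level of the collagen, endothelial and interferon response lists. Different value distributions of the groups' arrays are argued against, because the fibroblast list's median was 0.589 after quantile normalization and 0.569 before, whereas chance could not be excluded for the number of lists called: 75 of 100 splits gave at least the real 6 and the highest other 16, and with neighbouring arrays kept together 24 of 35 splits did and the highest other gave 14. A lower share of keratinocytes in the cKO samples cannot be told apart from a change within the stroma: the endothelial list, with 12 of 20 members above background, rose by about as much as the fibroblast list (difference of medians 0.0482, bootstrap standard error 0.338). The T and NK cell, mast cell and adipocyte lists lay lower by 0.451, 0.453 and 0.534, each within 2 standard errors, with 6 of 23, 3 of 10 and 4 of 11 members above background. By the rule first written these values would have counted for a lower share; the demands that the lists lie mostly above background and that basal keratinocyte genes (median -0.01) be lower were added after the values were seen, and the loss of G9a stays open.

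The third pattern is large changes with little spread within each group, as in Gadl1 and Akr1c13: 28 genes changed over 2-fold with an SD under 0.2 in both groups, 25 of them higher in cKO. Strain sequence flanking the targeted locus is argued against as the source of the pattern, since 26 of the 27 genes placed in the annotation lie on other chromosomes than Ehmt2. Chromosome segments of different strains stay open: 2 of 27 placed genes, Akr1c12 and Akr1c13, lay within 5 measured genes of another, at percentile 81.47 of 10000 random draws, and since the draws' mean was 0.404, a percentile under 95, the bound first set against this explanation, does not argue against it. Strain differences at scattered loci and cross-hybridisation between those paralogs were not tested, and the loss of G9a stays open. Whether the mirroring of neighbouring arrays lowered the SDs was not tested either. Gadl1 lay below the median of the nonspecific controls on all 6 WT arrays, so its small SD there is one of values at background.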

How the results depend on the processing

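The neighbouring-pair term, alone and after quantile normalization, was chosen after seeing the data. The direction and call of Ehmt2 probe set 2 held in each alternative that read it alone, and the mean over both probe sets changed by -1.1; probe set 1 passed after quantile normalization (0.2427, adjusted p = 0.0145) and ranged from 0.07446 to 0.1733 with single arrays left out, passing without WT replicate 9 (adjusted p = 0.0486). The number of genes called, 7830, was 4362 (2060 higher) among genes above the 50th percentile, where fewer genes were tested, 304 with the 2-fold limit, 13551 over single probe sets (6928 higher, 6623 lower, 502 over 2-fold), 3249 with cell makeup covariates (1923 higher, 1326 lower), 4228 with the neighbouring-pair term (2459 higher, 1769 lower) and 3933 with that term after quantile normalization (2588 higher, 1345 lower). With single arrays left out it ranged from 7016 to 7718. With the replicate block it was 3055 (1668 higher, 1387 lower). The deviations of same-numbered arrays correlated at 0.0491, -0.298, -0.145 and -0.0662, and 0 of 8 such arrays correlated best with their own number. Because each of these arrays also mirrors its neighbour, these values cannot decide whether the shared numbers pair the tumours.

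Lists called higher and lower, 3 and 3, were 0 and 0 with an estimated correlation, 14 and 7 with fry, 3 and 1 after quantile normalization (also with the neighbouring-pair term), 5 higher above the 50th percentile and 0 higher with cell makeup covariates. Among called lists, the medians at which a call was lost were, with an estimated correlation, -0.4029 (stress keratinocyte), -0.1465 (replication), 0.4472 (interferon), 0.5687 (fibroblast), 0.5206 (endothelial) and -0.09542 (ribosomal); after quantile normalization, -0.06832 (replication) and -0.004909 (ribosomal), the same with the neighbouring-pair term; for replication, -0.1406 above the 25th and -0.1465 above the 50th percentile; and with cell makeup covariates, -0.4662 (stress keratinocyte), -0.1285 (replication), 0.2331 (interferon) and 0.09499 (fibroblast). Over 24 settings, adjusted p ranged up to 0.8658 for each called list, from 0.001668 (stress keratinocyte), 0.0005589 (replication and endothelial), 5.662e-05 (interferon and fibroblast) and 0.0007333 (ribosomal). The stress keratinocyte list ranged from -0.489 to -0.3362 with single arrays left out and lost its call without WT replicate 2 (adjusted p = 0.0518). Calls were gained by class II genes (2.008 above the 50th percentile, 1.186 with the replicate block), T and NK cell markers (0.2528 above the 50th percentile), matrix proteases (-0.6562 with the replicate block) and xenobiotic genes (-0.3587 with cell makeup covariates). With these covariates the test's direction turned for endothelial markers (median 0.1786), class I genes (-0.4668) and immediate early genes (-0.2329), and the change turned for H2-Ab1 (-0.1343), Plat (-0.1103), Psme1 (-0.2462), Lrg1 (-0.01173), Ier2 (-0.1095) and Cox6a1 (-0.02563); Cd44 turned with the mean over probe sets (0.01752). The covariates are built from genes that differ between the groups. The distance difference passed over all genes (-0.004982, exact permutation p = 0.0332) and as Euclidean distance (-6.104, exact permutation p = 0.0256), and ranged from -0.01558 to 0.0756 (without cKO replicate 1) with single arrays left out. Apart from these cases the cause of a changed call was not tested. Of 186 named genes other than Ehmt2, 31 lost their call with the neighbouring-pair term, 9 after quantile normalization and 79 with cell makeup covariates, where the 6 that turned are not counted, 68 with the replicate block, 40 with the neighbouring-pair term after quantile normalization and 12 with the mean over probe sets. Signals near the nonspecific controls limit what dim genes can show.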

Other observations

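The genes named in the first paragraph were chosen after their values were seen, and the test in the second was prompted by large increases already seen.

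Some abundant markers of the connective tissue, fat and mast cell lists did not pass the test. Postn, which encodes the matrix protein periostin, read 9.11 ± 0.74 in WT and 8.87 ± 0.84 in cKO tumours (SD, n = 6 and 7, limma adjusted p = 0.668), and Fbln1 read 10.51 ± 0.37 and 10.68 ± 0.31 (adjusted p = 0.447). Fabp4, a fatty acid binding protein of adipocytes, read 9.04 ± 1.70 and 8.48 ± 1.01 (adjusted p = 0.540). Cma1, a mast cell chymase, differed by -0.07 (adjusted p = 0.0707).

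Genes silent in WT tumours may have been switched on in cKO tumours more often than the reverse, a hypothesis tested on the same arrays. Against a level of 4.31, the upper quartile of the nonspecific controls, 19 genes crossed from background to at least 2-fold above it in cKO tumours and 6 the other way (two-sided exact binomial p = 0.0146, and 0.00661 for 19 and 5 genes with the neighbouring-pair term). Among all genes changed over 2-fold, Fisher's exact p was 0.0201, 0.0287 with the neighbouring-pair term and 0.133 after quantile normalization. The genes that rose from background included Gadl1, Xlr and Pate14 and also the stromal, vascular and blood-cell genes Col6a3, P4ha3, Cd93, Itgb3 and Slfn4, so a change in cell makeup is an open explanation, and Tll1 was among those that went below it by its group mean. Genes of one cell type can move together, so the genes are not independent.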
